A study of Mus musculus with 8 samples.

How the data were processed

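RNA sequencing libraries of 4 sorted populations of mouse hair follicle stem cells were used: Ctnnb1 Het and cKO cells, and LacZ-positive and LacZ-negative bulge cells of Axin2-LacZ mice, with 1 library each. Groups were taken from the sample labels. Per the labels' protocols, RNA was purified with a column kit, RNA integrity numbers were above a set limit, and libraries made with Illumina's TruSeq mRNA kit were run on a HiSeq instrument. Whether a library came from 1 mouse or a pool is not given in the sources used here. The 4 chromatin immunoprecipitation samples were not analysed here.

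Per the file headers, the authors deposited FPKM values, fragments scaled to transcript length and to the mapped fragments of the library, in 2 gene tables, 1 per pair of libraries. FPKM divides by a library total of fragments, so a few very abundant features can shift all other values. The short mitochondrial transfer RNA mt-Ts1 made up 20.6% to 28.1% of the summed FPKM of a library. Because FPKM also divides by length, this is not its share of fragments, which is unknown. The submitters' processing notes name TopHat2 2.0.4, TopHat, Cufflinks 2.1.1 and the builds mm9 and GRCm38 without their roles; the scaling, multi-read and strand settings are not given in the sources used here. The first table also holds a deposited log2 fold change of cKO over Het by the authors, used only for a check. It equals the log2 ratio of the FPKM columns within 0.01 in 18011 of 18107 rows with both values above 0; the other 96 are written as 0, as are all 2423 rows with a value above 0 in only 1 library. FPKM keep no counts, so depth is unknown and no counting interval was computed. Exact zeros occur beside high values, and a gene at 0 is described only as listed at 0.

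Each table holds 32091 rows with 28792 symbols. Coordinates are those of the tables and are taken as mm9: on chromosome 7 they reach 152509964, beyond the last gene end of GRCm38 (145324059 in the reference gene table). They mark intervals that 12167 rows share with another row, so overlapping genes can share reads. The first table held 25 symbols turned into dates by a spreadsheet, which were restored from the Ensembl identifiers through a gene name table; 28040 of 32091 identifiers were found there. Rows of the same symbol were summed. No column of per-sample values was left unused.

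For each pair the log2 of (FPKM + 1) of the first library over that of the second was taken for genes at 1 FPKM or more in either library; on this scale changes of low genes are understated. With 1 library per group there is no test. Genes at a log2 difference of 1 or more, or -1 or less, were counted as differing by 2-fold or more. The 25 gene lists, with 443 entries and 422 distinct genes, of which 6 are in neither table, were fixed before the data were examined. A list's median was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression; a list stood apart at or below percentile 2.5 or at or above 97.5, and lists with fewer than 5 measured members got values only. These percentiles describe the libraries and are not p-values. The value of 1 list in the second pair is not reported here. The overlap of the pairs was set beside n1 × n2 / N for independent lists.

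Named genes were fixed by rule before the data were examined: Ctnnb1 and Axin2; in each pair the 10 highest and 10 lowest log2 differences among genes at 5 FPKM or more in either library, without Gm, LOC, Rik, Mir, Snor, Rnu, n-R and -ps names (matched with case, so names in capitals such as SNORD stayed in); of each list described, the members with the largest differences, and any Wnt target; and of the overlap the 10 genes with the largest smaller difference. The rankings without features listed at 0 or with small RNA and clone names were added after the values were seen. Levels of some further members, such as Cd34, Krt15, Ptch1 and Lgr5, were added in the same way.

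The alternatives planned beforehand were pseudocounts of 0.1 and 5, no minimum, a minimum of 5, centring on the median of genes at 5 or more in both libraries, upper-quartile scaling, the highest row per symbol, leaving out small RNA, Gm and Rik symbols (with clone names and mitochondrial transfer RNAs), and random lists matched only on size. Leaving out genes listed at 0, keeping only genes alone in their interval, and leaving out both small features and zeros were chosen after seeing the data. The steps were tested on simulated pairs: of 100 lists with no shift, 7 stood apart in a simulation of the first pair (13014 genes) and 8 in that of the second (13283 genes), and of 10 lists shifted 1.25-fold, 10 and 7 were found. These simulations used lists of random genes and gave all genes independent noise of the same spread. They do not show how often a list of genes that vary together would stand apart. In a copy of each pair with a library set against itself, without noise, all 200 genes changed 4-fold were counted, with 0 false ones. That setting fixes this outcome: it checks the computation and does not show how many genes pass the line through noise. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.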

Results

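The series profiled hair follicle stem cells, the cells of the follicle bulge that rebuild the hair at each cycle, sorted from mouse back skin by flow cytometry. Of its 8 samples, 4 are RNA sequencing libraries and form 2 comparisons, with 1 library in each group. In the first, K15CrePGR mice carried 1 or 2 floxed copies of Ctnnb1, the gene of β-catenin (labelled Het and cKO), together with a Rosa-YFP reporter; they were females of day 99. In the second, male mice of day 24, heterozygous for the Axin2-LacZ reporter (Axin2LacZ/+), were used as follicles passed from rest (telogen) to growth (anagen). Their bulge cells were sorted by the reporter's activity into LacZ-positive and LacZ-negative cells. The labels differ on the stage of the first pair: the growth protocol names telogen and the series design names the start of anagen. The other 4 samples, chromatin immunoprecipitation libraries for TCF3, TCF4 and TLE and their input, were not analysed here. Values are FPKM, which keep no read counts, so the depth behind each value is unknown. No difference below has a replicate check, and all of them describe these libraries only.

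The targeted gene was read first. Ctnnb1 (ENSMUSG00000006932, mm9 chromosome 9, 120833572 to 121186315, an interval the table gives to 4 genes) stood at 370 FPKM in the cKO-labelled library and 251 in the Het-labelled library, a log2 difference of 0.55. A gene-level FPKM does not resolve the deleted part of the gene, so this value does not check the genotype labels, and because it runs opposite to a loss, the libraries are called by their labels throughout. In the LacZ pair Ctnnb1 stood at 348 FPKM in LacZ-positive and 344 in LacZ-negative cells. Axin2 (ENSMUSG00000000142, mm9 chromosome 11, 108781662 to 108812097), a target gene and feedback inhibitor of Wnt signalling, stood at 2.12 FPKM in the cKO-labelled library and 16.3 in the Het-labelled library, a log2 difference of -2.47. It stood at 19.0 FPKM in LacZ-positive and 9.10 in LacZ-negative cells, in the direction of the sort. The log2 difference was 0.98, just under the 2-fold line through the pseudocount of 1. The FPKM themselves differed by more than 2-fold. Centring on the pair's median of -0.17 for genes at 5 FPKM or more would also put Axin2 above the line. The sex labels could be read from the tables: Xist was at 273 and 329 FPKM in the cKO-labelled and Het-labelled libraries and at 0.139 and 0.311 in the LacZ pair, where Ddx3y was at 27.3 and 25.2.

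The first comparison asks which genes of the stem cells differ when both copies of Ctnnb1 are floxed. Wnt target genes, cell cycle genes and hair germ genes were lower in the cKO-labelled library, and immediate early genes were higher. Of the Wnt target list, 14 of 20 genes reached 1 FPKM, 12 of them were lower and 3 were lower by 2-fold or more: Wif1 (-2.69), Axin2 (-2.47) and Cd44 (-1.22). Lgr5, a stem cell receptor for R-spondins, went from 183 FPKM in the Het-labelled to 108 in the cKO-labelled library, and Ccnd1 from 42.2 to 23.8. The list's median was -0.46 on the log2 scale, at percentile 0 of 10000 random lists of the same size and expression. With only the 8 members that share their interval with no other gene, which leaves out Axin2, Lgr5, Ccnd1 and Cd44 among others, the median was -0.18 and no longer stood apart.

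Of the cell cycle list, 31 of 33 measured members were lower, 16 of them by 2-fold or more. The median was -0.93, at percentile 0. Top2a, the topoisomerase of dividing cells, stood at 1.11 FPKM in the cKO-labelled and 11.6 in the Het-labelled library. Cenpf stood at 0.103 and 4.04, Cdk1 at 1.19 and 8.84, and Ccna2 at 0.926 and 5.80. Most members lay under 10 FPKM in both libraries, where the pseudocount of 1 compresses a ratio. Hair germ and matrix genes had a median of -0.26 (percentile 0.12), with 12 of 15 measured members lower; Foxi3 (-1.27) and Gli1 (-1.25), a readout of hedgehog signalling, were lower by 2-fold or more. The Shh pathway list, which shares Gli1 and Ptch1 with it, had a median of -0.15 (percentile 0.40, 10 measured), and Ptch1 stood at 16.6 against 29.4 FPKM.

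Immediate early and stress genes were all higher in the cKO-labelled library, 8 of 18 by 2-fold or more, with a median of 0.89 at percentile 100. Atf3 stood at 246 against 75.8 FPKM, Nr4a1 at 123 against 41.1, Fos at 938 against 348 and Dusp1 at 388 against 148. Sebaceous and lipid genes had a median of 0.29 (percentile 99.9; 12 measured, Scd3 at 1.20 and Acaca at 0.95). Basal and hyperproliferation genes had a median of 0.28 (percentile 99.8), with 12 of 14 higher: Krt6b (1.32) and Krt6a (1.29), keratins of the companion layer and of activated epidermis, were higher by 2-fold or more, and Krt17 (-1.41) was lower.

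Bulge stem cell genes did not stand apart as a list (median 0.07, percentile 16.4, 20 measured): Cd34 stood at 752 against 645 FPKM and Krt15 at 7528 against 6208. Among them Krt24 was lower by 2-fold or more (102 against 278 FPKM). The BMP and TGF-β list had a median of -0.11 (percentile 0.14), of which 23 of 24 members lay within 2-fold and Tgfb3 was at -2.53; with a minimum of 5 FPKM its median was 0.033. Epidermal differentiation genes had a median of -0.13 (percentile 0.12), led by Sprr1b (-3.04), Sprr1a (-0.83) and Lor (-0.77). That median turned to 0.028 with a minimum of 5 FPKM and to 0.00019 with none, so it gives no stable direction. Lists that did not stand apart were Wnt receptors and transducers (0.08, percentile 62.7), although Lgr6 was at -3.16, Wnt ligands (0.12, percentile 82.3), hair shaft and inner root sheath genes (0.08, percentile 66.4), Notch (-0.02, percentile 10.9), FGF and EGF (0.05, percentile 36.2), p53 and cell death genes (0.15, percentile 90.7) and reference genes (0.17, percentile 78.1).

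Markers of other cell types were few and low in this pair, and their lists had fewer than 5 measured members. The medians were 0.38 for 4 leukocyte markers, of which Cd68 stood highest at 5.20 and 2.39 FPKM, 0.19 for 3 fibroblast markers (Col1a1 at 10.3 and 3.72 FPKM), 0.24 for 2 endothelial markers, -0.33 for 2 melanocyte markers, -0.12 for 3 muscle, adipocyte and blood markers and 0.34 for 3 Merkel and nerve markers. Secreted Wnt inhibitors, 4 measured, had a median of -0.46, and the single sex-linked gene measured, Xist, was at -0.27.

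Across the genome, 13014 genes reached 1 FPKM in either library; 234 were higher and 298 lower by 2-fold or more in the cKO-labelled library. Of these, 94 and 103 were listed at 0 in the other library, and 139 and 161 carried small RNA, clone, Gm or Rik names; without both kinds, 93 genes were higher and 133 lower. The 9396 genes at 5 FPKM or more in both libraries had a median of 0.07 and a central 95% between -0.50 and 0.61. All 20 genes named by the rule fixed before the data were examined were short features listed at 0 in 1 library, so the same ranking was taken, after the values were seen, among genes above 0 without such names. The lowest were Braf (-3.51), the amino acid transporter gene Slc38a4 (-3.22), Lgr6 (-3.16), a receptor of the upper follicle, Bgn (-3.09), Sprr1b, Wif1, Fam40b (-2.69), Top2a, Tgfb3 and Axin2. The highest were Dlk1 (3.31, 21.6 against 1.28 FPKM), a Notch-related inhibitor of differentiation, Clec3b (2.70), Synj1 (2.36), Scrg1 (2.05), Lrguk (2.03), Ppp1r3c (1.95), Adamtsl3 (1.92), Pcolce2 (1.91), Sphkap (1.87) and Sncg (1.77). Of these 20 genes, 5 share an interval with other genes, so reads of neighbours can enter their values: Synj1 (5 genes in the interval), Braf and Pcolce2 (4 each), Top2a (3) and Axin2 (2).

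The second comparison asks how bulge cells with Axin2 reporter activity differ from those without it. Cell cycle and epidermal differentiation genes were higher in LacZ-positive cells, and bulge and hair germ genes were lower. The 9252 genes at 5 FPKM or more in both libraries had a median log2 difference of -0.17, so for lists with 5 or more measured members the distance from that median is given beside the list's own. Of the cell cycle list, 34 of 35 measured members were higher, 28 by 2-fold or more, with a median of 1.75 (1.92 above all genes, percentile 100). Ccna2 stood at 20.1 FPKM in LacZ-positive and 2.33 in LacZ-negative cells, Cdk1 at 28.8 and 4.15, Cenpf at 11.0 and 1.08, and Foxm1, a driver of mitotic gene expression, at 10.3 and 0.995.

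Of the epidermal differentiation list, 20 of 22 genes were measured, 19 were higher and 14 by 2-fold or more, with a median of 1.18 (1.35 above all genes, percentile 100). Defb6 stood at 1031 FPKM in LacZ-positive and 241 in LacZ-negative cells, Krt79 at 362 and 119, Sprr1a at 54.5 and 17.6, and Sprr1b at 4.30 and 0.555. Bulge stem cell genes had a median of -0.51 (-0.34 relative to all genes, percentile 0), with 14 of 20 lower and 4 by 2-fold or more: Fgf18 (-1.61), Tbx1 (-1.31), Cd34 (-1.21) and Foxp1 (-1.06, or -0.89 after centring). Cd34 (5 genes in the interval) and Foxp1 (4) share an interval, so reads of neighbours can enter their values. The list kept its side in all 10 alternatives, also with only genes alone in their interval. Krt15, a bulge keratin, is listed at 0 in LacZ-negative cells and at 5951 FPKM in LacZ-positive cells; an exact 0 in such a table can be a failed estimate, so no fold is given. Through Krt15 alone the list's mean is 0.11, opposite in sign to its median.

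Hair germ and matrix genes had a median of -0.50 (-0.33 relative to all genes, percentile 0.06), with Dlx3 (-1.97), Msx2 (-1.41), Msx1 (-1.40) and Dlx2 (-1.33) lower by 2-fold or more. With no minimum the median was -0.044 and the list no longer stood apart. Of the BMP and TGF-β list, 6 of 24 members were lower by 2-fold or more and none was higher, among them the BMP antagonist Nog (-1.98) and the BMP response genes Id3 (-1.42), Id1 (-1.37) and Id2 (-1.26). The remaining members past the line, Smad7 and Smad9, fell inside it after centring (-0.84 and -0.83). The list's median of -0.30 (-0.13 relative to all genes) lay at percentile 3.70, and the list stood apart with pseudocount 0.1 (-0.37) and with a minimum of 5 FPKM (-0.49). Immediate early and stress genes had a median of 0.22 (0.39 above all genes, percentile 100), with Egr2 (1.88) and Fosb (1.05) higher by 2-fold or more.

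The Wnt target list did not stand apart in this pair (median -0.04, percentile 73.5, 14 measured), and its sign turns to 0.13 when taken relative to all genes. Within it Tnfrsf19 (1.60) and Apcdd1 (1.38) were higher by 2-fold or more and Axin2 was at 0.98, while Lgr5 stood at 43.9 and 41.3 FPKM. Wnt receptors and transducers (-0.24, -0.07 relative to all genes, percentile 16.5) went both ways, with Lgr6 (1.51) and Fzd10 (1.10) higher and Fzd9 (-2.04) and Fzd1 lower by 2-fold or more. Fzd1 fell inside the line after centring (-0.89). Among Wnt ligands (-0.0023, 0.17 relative to all genes, percentile 73.8) Wnt16 (1.35) and Wnt3 (1.12) were higher by 2-fold or more. Basal and hyperproliferation genes (-0.15, 0.02 relative to all genes, percentile 84.2) also went both ways: Ly6a (1.69) and Gata6 (1.45) were higher, and Krt6a (-1.50) and Krt6b (-1.35) lower. The other lists within the central range are given with the median, then the median relative to all genes. They were sebaceous and lipid genes (0.14, 0.31, percentile 97.4, Fabp5 at 1.36), p53 and cell death genes (0.07, 0.24, percentile 97.1), Notch (0.04, 0.21, percentile 91.3), FGF and EGF (-0.06, 0.11, percentile 70.0), Shh (-0.28, -0.11, percentile 14.6), hair shaft and inner root sheath genes (0.15, 0.32, percentile 86.7) and reference genes (-0.18, -0.0058, percentile 82.4). Some of these calls depend on the setting: sebaceous and lipid genes stood apart in 4 of 10 alternatives, with a median of 0.52 at a minimum of 5 FPKM, p53 and cell death genes in 3 of 10, and FGF and EGF genes at -0.47 with a minimum of 5 FPKM. With no minimum, hair shaft and inner root sheath genes stood apart at 0.14.

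Beside the epidermal and cell cycle lists, leukocyte markers had a median of 0.89 (1.06 above all genes, percentile 99.3, 5 measured), at levels up to 3.26 FPKM for Cd74, and melanocyte markers a median of 0.27 (0.44 above all genes, percentile 90.1, 5 measured), which stood apart with no minimum (0.20). The medians of lists with fewer than 5 measured members were 0.25 for 4 fibroblast markers, 0.17 for 1 endothelial marker, 0.03 for 4 muscle, adipocyte and blood markers, -0.66 for 4 secreted Wnt inhibitors and 0.16 for 4 sex-linked genes.

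**Figure D1:**
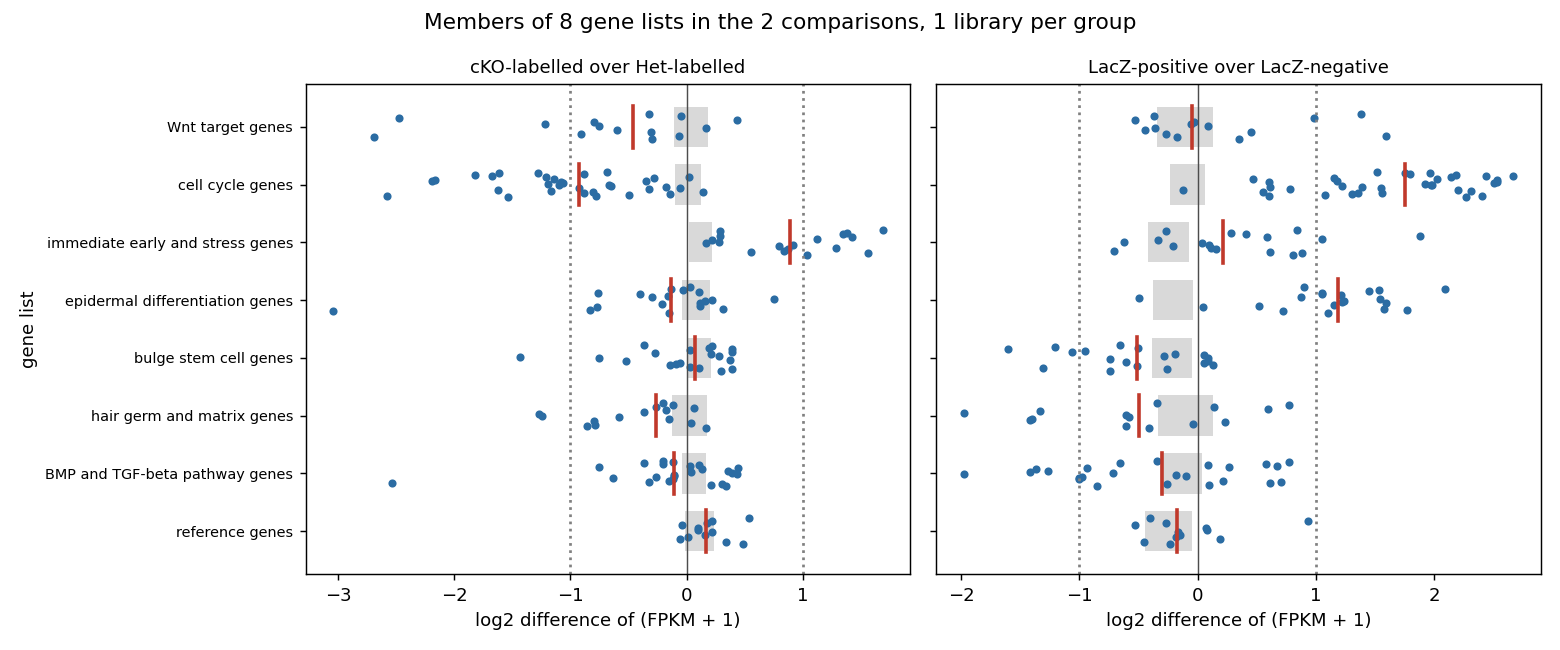
Log2 differences of (FPKM + 1) on the horizontal axis for the measured members of 8 fixed gene lists on the vertical axis, in the cKO-labelled over Het-labelled (left) and LacZ-positive over LacZ-negative (right) comparison. Each point is a gene, the red line the list's median, the grey bar the central 95% of medians of 10000 random matched lists and the dotted lines the 2-fold line; Krt15, listed at 0 in LacZ-negative cells, is not drawn. Cell cycle genes lie to the left in the first pair (median -0.93) and to the right in the second (median 1.75).

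Of 13283 genes that reached 1 FPKM in either LacZ library, 620 were higher and 346 lower by 2-fold or more in LacZ-positive cells; with differences centred on the median these were 804 and 224, so the share of higher genes went from 64.2% to 78.2%. Without small RNA, clone, Gm and Rik names and genes listed at 0, 394 were higher and 190 lower. The rule for named genes again gave short features listed at 0 in 1 library, with Krt15 as the only other gene. Under the ranking chosen after the values were seen, the highest were Alox5ap (2.75), Ccna2 (2.67), Spag5 (2.62), Cdk1 (2.53), Cenpf (2.53), Foxm1 (2.51), Racgap1, Grap (2.45), Ccnb1 (2.44) and Top2a (2.41), most of which act in mitosis. The lowest were Krt25 (-4.51, 1.13 against 47.7 FPKM), a keratin of the inner root sheath, Supv3l1 (-2.34), Ddit4l (-2.20), Myoc (-2.12), the Wnt receptor gene Fzd9 (-2.04), Sncg (3.62 against 17.5 FPKM), Igfbp6 (-1.98), Nog (-1.98), Dlx3 (-1.97) and the retinoic acid hydroxylase gene Cyp26b1 (-1.93). Here Foxm1 (4 genes in the interval), Grap and Top2a (3 each), and Alox5ap, Ccna2, Racgap1 and Myoc (2 each) share an interval. Krt25 was the only measured member of the hair shaft and inner root sheath list past the 2-fold line. Krt26, Krt27, Krt28 and Krt73 of that list stayed under 1 FPKM in both populations. The difference thus describes Krt25 and not the inner root sheath keratins as a group.

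Set side by side, the 2 comparisons share no library. Of 12499 genes that reached the minimum in both, 84 were lower in the cKO-labelled library and higher in LacZ-positive cells, where independent lists would share 8.06, and 16 of the 84 belong to the cell cycle list. The other combinations held 30 genes higher in the cKO-labelled library and lower in LacZ-positive cells (3.60 for independent lists), 23 lower in both (4.90) and 39 higher in both (5.91). Features with small RNA, clone, Gm or Rik names made up most of the same-direction genes: among the 10614 genes with other names and above 0 in all libraries, the counts were 55 and 16 for the opposite directions (3.77 and 1.23 for independent lists) and 0 and 2 for the same direction (2.02 and 2.29). Across all 12499 genes, which are not independent replicates, Pearson's r of the log2 differences was -0.01 and Spearman's rho -0.15; across the 10614 genes they were -0.26 and -0.17. The first 10 of the 84 by the smaller of their differences were small RNA or clone features, and among the 55 the first 10 were Top2a, Cenpf, Cdk1, Ccna2, Sprr1b, Slc38a4, Braf, Ccnb1, Pbk and Cdca3. Pbk and Cdca3 also act in cell division but lie outside the fixed cell cycle list, as do others of the 55. Slc38a4 stood at 0.345 and 11.5 FPKM in the cKO-labelled and Het-labelled libraries and at 11.2 and 2.71 in LacZ-positive and LacZ-negative cells, and Lgr6 at 2.04 and 26.2, and 34.9 and 11.6.

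**Figure D2:**
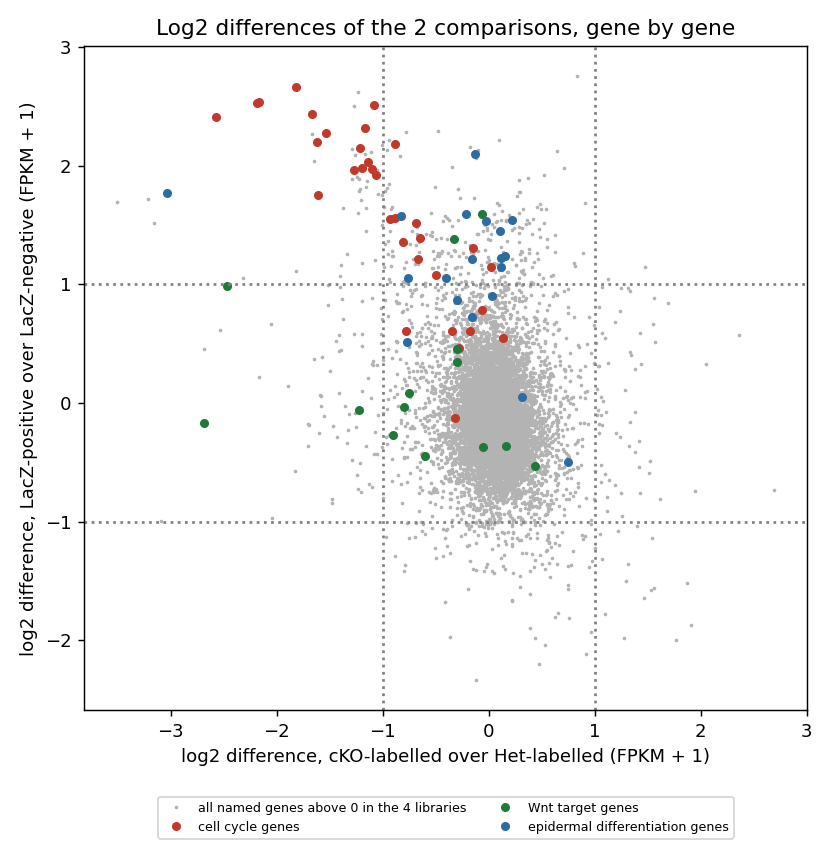
Log2 difference of (FPKM + 1) of the cKO-labelled over the Het-labelled library (horizontal) and of LacZ-positive over LacZ-negative cells (vertical) for the 10614 genes above 0 in all 4 libraries and without small RNA, clone, Gm or Rik names, each point a gene. Dotted lines mark the 2-fold line. The upper left corner holds 55 genes, 16 of them from the fixed cell cycle list (red), which does not hold all genes of cell division. The lower right corner holds 16 genes.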

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

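Leaving out genes listed at 0, genes that share an interval, or small features together with zeros was chosen after seeing the data. No replicate could be left out and no pairing was possible with 1 library per group, and unknown depth limits all counts, most of all for genes under 5 FPKM. Of 351 recomputed list medians 334 kept their side of the limits, 12, all in the second pair, newly stood apart, 2 no longer did, and 3 of lists that stood apart changed sign. Of the 334, 18 changed sign within the central range. Centring moves a list and its random lists alike, so it could not change a list's side. Leaving out small features was applied only to gene counts, not to list medians or named genes. The cell cycle median ran from -1.51 to -0.38 in the first pair and from 1.01 to 2.28 in the second, and immediate early genes in the first from 0.82 to 0.90, all on their side of the limits. Of 1260 recomputed named differences 1193 kept their side of the 2-fold line and 67 fell inside it, 54 of them with pseudocount 5, which shrinks low genes by construction. Changing the minimum or leaving genes out does not alter a retained gene's difference, and the smaller pseudocount can only enlarge it. Those settings could not move a gene inside the line, so the 1193 include outcomes that were not tested. Only pseudocount 5, centring, upper-quartile scaling and the highest row per symbol could do so. Apart from the shrinkage by pseudocount 5, the cause of the changes was not tested unless stated.

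Epidermal differentiation genes in the first pair turned to 0.00019 with no minimum and to 0.028 with a minimum of 5, and BMP and TGF-β genes to 0.033 with a minimum of 5. Wnt target genes in the first pair went to -0.18 with only genes alone in their interval, which leaves 8 members and no Axin2; hair germ genes in the second went to -0.044 with no minimum, which adds genes near 0.

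Genes higher and lower in the cKO-labelled library numbered 234 and 298. They were 144 and 159 with pseudocount 5, 95 and 137 without small RNA, Gm and Rik symbols, 140 and 195 without genes listed at 0, 108 and 131 alone in their interval, and 93 and 133 without small features and zeros. Genes higher and lower in LacZ-positive cells numbered 620 and 346. They were 282 and 178 with pseudocount 5, 396 and 194 without small features, 315 and 174 alone in their interval, and 394 and 190 without small features and zeros; the lower ones were 528 with pseudocount 0.1 and 224 after centring. Removing features lowers these counts by construction. With no minimum the counts cannot move, since under pseudocount 1 a gene below 1 FPKM cannot reach the line.

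Genes lower in the cKO-labelled library and higher in LacZ-positive cells numbered 84. They were 141 with pseudocount 0.1, 28 with pseudocount 5, 43 with a minimum of 5, 55 without small features, 42 alone in their interval and 55 without small features and zeros. The reverse combination, 30 genes, was 50 with pseudocount 0.1, 19 with pseudocount 5, 19 after centring, 17 without small features, 18 alone in their interval and 16 without small features and zeros. Genes higher in both, 39, were 60 with pseudocount 0.1, 2 without small features, 8 without genes listed at 0, 5 alone in their interval and 2 without small features and zeros. Genes lower in both, 23, were 1, 7, 5 and 0 without small features, without genes listed at 0, alone in their interval, and without small features and zeros.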

Other observations

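The checks of library scaling, hair cycle timing, isolation handling and other epidermal cells were chosen after the results were seen. The test of shared reads was set before its result was seen. The scaling check sets a list's median against the random lists by which that list stood apart, so it could not come out otherwise.

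The 16 genes higher in the cKO-labelled library and lower in LacZ-positive cells, among named genes above 0, were read after the values were seen. They include S100a4 (5913 against 2139 FPKM in the cKO-labelled and Het-labelled libraries, 268 against 837 in LacZ-positive and LacZ-negative cells), Angptl7 (259 against 89.2, and 18.4 against 56.8), Krt6a (415 against 168, and 170 against 480), Krt6b, Mfge8, Sncg, Pcolce2, Igfbp6 and Hpgd. Krt6a and Krt6b are keratins of the companion layer and the inner, non-stem layer of the bulge. Angptl7 and Pcolce2 lie in intervals of 4 genes each, so reads of neighbours can enter their values. The opposite 55 genes, 16 of them from the cell cycle list, also hold Lgr6, Slc38a4, Serpinb11 (9.98 against 53.7, and 7.91 against 3.30), the cornified envelope genes Lce1m (17.9 against 38.4, and 15.5 against 3.23) and Sprr4 (1.31 against 4.65, and 132 against 29.3). The fixed list does not hold all genes of cell division: Pbk, Cdca3, Racgap1, Cenpa, Spag5, Kif22, Nuf2 and Cdca8, also among the 55, lie outside it.

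Cell cycle genes were lower in the cKO-labelled library and higher in LacZ-positive cells. In the check of library scaling, the list lay -0.995 from the median of all genes in the first pair and 1.919 in the second. Its medians, -0.93 and 1.75, lay outside the central range of random lists. That is how the list stood apart, so scaling got no separate test. Reads shared with overlapping genes are argued against by the 21 members alone in their interval, whose median in the first pair was -0.884. In the first pair, hair cycle timing of the mice cannot be told apart from genotype, since hair germ genes were also lower (-0.260) and each genotype has 1 library. In the second pair, where timing was not tested, the lists moved apart: hair germ genes were lower (-0.50, or -0.044 with no minimum, where they no longer stood apart) while cell cycle genes were higher (1.75). A lower share of cycling cells in the cKO-labelled library, and a higher share among LacZ-positive cells, may underlie the pattern and is a hypothesis that needs replicates.

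Immediate early and stress genes were higher in the cKO-labelled library, 0.823 above the median of all genes and outside the range of random lists. That range is how the list stood apart, so scaling got no separate test. Handling during cell isolation may raise such genes, and the heat shock members Hspa1a, Hspa1b, Hsph1 and Dnajb1 had a median of 0.247 against 0.07 for all genes. That is far below the 0.89 of the whole list. Handling and genotype cannot be told apart, because each genotype has 1 library; a difference by genotype stays open and untested.

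Epidermal differentiation genes were higher in LacZ-positive cells, 1.352 above the median of all genes. Here, too, scaling got no separate test. Cells from other parts of the epidermis in the LacZ-positive sort may contribute. The 5 most abundant members, by the mean of the LacZ-positive and LacZ-negative values, had a median of 1.219, while the bulge list was lower. Both lists had already been seen to move this way, so these values do not tell such cells from a difference in state. Krt10 stood at 1491 against 633 FPKM, Krtdap at 1318 against 594, Defb6 at 1031 against 241 and Krt77 at 759 against 326. The fifth, Sbsn, stood at 305 against 295, close to equal. A mixture with a single cell type rich in Sbsn would raise it too. On the log2 scale Sbsn was at 0.048, above the all-gene median of -0.17, as the check had asked of each of the 5. Both populations are labelled as bulge cells, but how far a gate on bulge surface markers removed other epidermal cells was not tested. Cd34 of the bulge list, which shares its interval with other genes, was lower by 2-fold or more in LacZ-positive cells. Ly6a of the basal list was higher by 2-fold or more there, while Krt6a and Krt6b of that list were lower. All 5 epidermal genes were also abundant in LacZ-negative cells, which does not tell whether other epidermal cells were present in both sorts. A difference in state between Axin2-reporter cells and the rest of the bulge stays open and untested.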
